A study of Mus musculus with 6 samples.

How the data were processed

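Single-cell RNA-seq was carried out on smooth muscle cells sorted from the aorta of 12-week-old mice that carry Nkx2-5-Cre and the mT/mG reporter. In this reporter a cell makes membrane tdTomato until Cre removes the tdTomato cassette, after which the cell and its descendants make membrane GFP. GFP cells therefore descend from cells that expressed Nkx2-5, a transcription factor of the early heart, and RFP cells are those in which the reporter was not recombined. Per the labels' protocols, segments were digested enzymatically in the cold, and viable single cells that stained for ITGA8 and were positive for GFP or RFP were sorted and loaded on the 10x Genomics Chromium 3' platform, which captures the 3' ends of transcripts with unique molecular identifiers (UMIs). The labels give 6 groups with 1 library each, namely GFP and RFP cells of the aortic root, GFP and RFP cells of the ascending aorta, RFP cells of the arch and RFP cells of the descending aorta. The labels do not state how many animals each library came from.

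The deposited files hold UMI counts per gene and barcode as whole numbers, with no normalization, for 32287 features that include eGFP and tdTomato. The matrices were written by Cell Ranger 7.0.0 per the file headers, and the submitters' processing notes name Cell Ranger, Seurat 4.3 and the mm10 genome. The gene annotation that the authors counted against is not given in the sources used here. The 54157 deposited barcodes equal, library by library, the cell numbers that the labels state before filtering. The labels also state smaller numbers after filtering, from 987 in the descending library to 8577 in the ascending RFP library, but the filter behind them is not given in the sources used here. A filter of this work's own was applied instead, so the cells below are not the authors' final cells.

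Barcodes with at least 1000 detected genes and at most 10% mitochondrial UMIs were kept, which left 38513 cells. Scrublet, called through scanpy 1.11.5, marked 60 of them as doublets (0.156%), 55 of which were in the descending library. At this rate the doublet caller did not work, so removing these 60 cells, which left 38453, does not count as doublet removal. Cells of all libraries were clustered together without integration on 2000 variable genes and 30 principal components, with mitochondrial, ribosomal protein, sex-linked marker and reporter features left out of the variable genes. The Leiden method (leidenalg 0.10.2, igraph 0.11.9) was run at resolution 0.8 on a graph of shared neighbours among the 20 nearest cells, and gave 18 clusters. All 9 markers of smooth muscle were detected in at least 50% of the cells of every cluster. Clusters were not named as subtypes, and 15 of them were summed as a pool.

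The rule that formed the pool was set after the clusters had been seen. A cluster was left out when at least 2 markers of another cell type were among its 10 leading genes and at least 3 markers of that type were detected in 20% of its cells at 2 times the level elsewhere. It was also left out when the median UMI count of its cells was under 0.333 of the median of their own library, when fewer than 3 smooth muscle markers reached 50% of its cells, or when it held fewer than 20 cells. Clusters 13, 16 and 18 were left out. Fibroblast markers lead cluster 13, cells of low UMI count make up cluster 16, and cluster 18 is myeloid-like. The pool holds 37320 cells.

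UMI counts were summed over the pool per library and divided by the pooled total of the library, and are given as CPM. Log2 ratios between libraries, and the fold limits of the rules, are of CPM plus a pseudocount of 5. Folds printed for a gene, with or without an interval, are ratios of CPM without the pseudocount. For genes of low CPM these folds are larger than the ratios that the fold limits apply to. Each group is 1 library, so there is no replicate check of any difference and no p-value is given for one. CPM values carry exact Poisson 95% intervals, ratios carry exact conditional binomial ones, and shares of cells carry exact Clopper-Pearson ones. These intervals cover counting error only and leave out the variation between animals and between sorts. Where a library had 0 counts of a gene, its floor was taken as 3 counts of the library total. A fold against this floor is a lower bound only apart from the counting error of the other library. A share of 0 cells likewise carries the limit of 3 counts over the cells in place of an interval. A gene was set apart between 2 libraries when CPM plus 5 differed at least 1.5-fold and CPM reached 20 in one of the libraries compared. Mitochondrial, ribosomal protein, haemoglobin, Xist, Tsix, Y-linked, clone-named and immediate early genes were left out of this rule.

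Named genes followed a fixed rule of size. For lineage it took up to 12 genes per direction, by the smaller of the log2 ratios in root and ascending aorta, and up to 5 genes per direction and segment at least 2-fold apart there and less than 1.25-fold apart in the other segment. For each RFP library it took the 8 genes highest above the next of the 4 RFP libraries and the 4 lowest below the next. For root against ascending aorta it took 8 genes per direction set apart in both lineages. It further took up to 4 members per list and comparison, and always Nkx2-5, Itga8, Acta2, Myh11, Eln and the reporter features. Results of 2 genes that the rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen. Of the 175 genes named by the rule or chosen later, 173 were matched by gene ID to the GENCODE vM21 annotation of GRCm38 (mm10), which gives the coordinates printed here.

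The 14 pathway lists covered contractile smooth muscle genes, elastic fibre genes, collagens, genes of modulated smooth muscle cells with proteoglycans, TGF-beta and BMP signalling, cardiac and second heart field genes, neural crest genes, Hox genes, vasoactive receptors and ion channels, Notch and PDGF signalling, chemokines and inflammation, immediate early genes of dissociation, nuclear genes of oxidative phosphorylation, and the cell cycle. The 15 marker lists covered smooth muscle, fibroblasts, endothelium, macrophages and other myeloid cells, lymphocytes, Schwann or glial cells, neurons, pericytes, cardiomyocytes, valve interstitial cells, chondrocytes, mesothelium, adipocytes, erythroid cells and melanocytes. For each pathway list the median log2 ratio was taken over members that reached 5 CPM in one of the libraries compared, with the counts of members at least 1.5-fold higher and lower. The percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries only. The groups, the comparisons, the lists, the naming rule and the cell filter were fixed before the data were examined, as were the alternatives unless said otherwise.

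Alternatives were a looser and a stricter cell filter, every deposited barcode, all cells that passed the filter, doublets kept, TMM size factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), totals without mitochondrial, ribosomal protein and immediate early genes, the mean of each cell's CPM, cells thinned to 2000 UMIs, a pseudocount of 1, an expression minimum of 5 CPM or none, a 2-fold size rule, and resolutions of 0.4 and 1.5. The stricter filter was applied to the cells of the pool without new clusters, and the looser one was followed by new clustering. Another was the edgeR quasi-likelihood test of lineage with segment as a covariate on the 4 library sums. Its 1 residual degree of freedom is the difference in lineage effect between the segments, not a replicate. Removing the top 5% of doublet scores per library, and taking ratios within clusters that hold 50 or more cells of both lineages, were chosen after seeing the data.

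The size rule was tested on simulated counts for the lineage comparison over 5886 genes, with 200 genes changed and a dispersion of 0.005. It recovered 50 of 50 genes set 2-fold higher and 47 of 50 set 2-fold lower in both segments, and 1 and 3 of 50 set 1.41-fold apart, with 0 false calls. The edgeR fit, tested on 5763 genes simulated for the same comparison, recovered 192 of 200 changed genes with 8 false calls. The random-list percentile, simulated for the root comparison over 9895 genes, put 8 of 100 unchanged lists outside the central 95% and 10 of 10 changed lists at percentile 100. In this simulation genes varied independently and all members of a changed list were set 2-fold higher, unlike in the real lists. An extreme percentile below therefore does not by itself mark a list out. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, matplotlib 3.10.9 and R 4.3.3.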

Results

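The series title contrasts smooth muscle cells of cardiac and of neural crest origin in the mouse aorta, and the 6 libraries hold ITGA8-positive aortic cells, sorted by reporter colour and segment, of mice 12 weeks of age that carry the Nkx2-5-Cre allele and the mT/mG reporter. Each group is 1 library, so no difference below has a replicate check, and the 95% intervals cover counting error only. The pool of 15 clusters held 5461 root GFP cells with 75145685 UMIs, 3878 root RFP cells with 47309544, 2905 ascending GFP cells with 45543811, 11703 ascending RFP cells with 161748008, 11581 arch RFP cells with 140750482 and 1792 descending RFP cells with 37309468. The median UMI count per cell ran from 11447 in the arch to 20064 in the descending library, which was thus the deepest per cell and the shallowest in sum.

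In sum over cells, reporter transcripts matched the sort. eGFP stood at 2491 CPM in root GFP and 2388 CPM in ascending GFP cells, against 8.44 to 11.5 CPM in the 4 RFP libraries. tdTomato stood at 264 to 282 CPM in the RFP libraries and at 0.106 and 0.220 CPM in root and ascending GFP cells. At least 5 eGFP UMIs were found in 98.7% of root GFP cells (98.3 to 98.9%) and 98.8% of ascending GFP cells (98.3 to 99.1%). In the RFP libraries such cells numbered 3 of 3991 in the root, 2 of 12008 in the ascending aorta, 1 of 11833 in the arch and 0 of 1869 in the descending aorta, where a count of 0 allows up to 0.161% (3 counts). Per cell tdTomato was less often seen, with at least 3 UMIs in 53.5% of root RFP cells (51.9 to 55.1%), 62.3% of ascending RFP (61.5 to 63.2%), 57.2% of arch (56.3 to 58.1%) and 77.0% of descending cells (75.1 to 78.9%), against 1 cell in each GFP library. Nkx2-5 itself (chromosome 17, 26838664 to 26845009, minus strand, in GRCm38) had 112 UMIs in root GFP cells (1.49 CPM, 1.23 to 1.79) and 28 in ascending GFP cells, and 0 in every RFP library. Its CPM in GFP cells was 23.5 times the floor of 3 counts in RFP cells of the root and 33.1 times that floor in the ascending aorta. These values leave out the counting error of the GFP counts, with 0.615 CPM (0.409 to 0.889) in ascending GFP cells.

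All libraries had the profile of contractile smooth muscle. The 9 smooth muscle markers summed to between 45890.4 CPM in the descending and 53182 CPM in the root RFP library. Myeloid markers summed to at most 3.78 CPM, Schwann or glial markers to at most 4.50, neuronal markers to at most 1.54, erythroid markers to at most 0.80, mesothelial markers to at most 0.65, lymphocyte markers to at most 0.32, melanocyte markers to at most 0.31 and adipocyte markers to at most 0.17. Endothelial markers reached 39.1 CPM in the descending library. Valve interstitial markers summed to between 1103 and 1296 CPM, mostly from Postn. The sort for ITGA8 sets which cells could be present. Of the cells kept by the filter, the pool held 94.9% in root GFP (94.3 to 95.5%), 97.2% in root RFP, 96.9% in ascending GFP, 97.5% in ascending RFP, 97.9% in arch RFP and 95.9% in descending RFP. Cluster 13, led by fibroblast markers, made up 4.45% of root GFP, 2.36% of root RFP, 2.5% of ascending GFP, 0.625% of ascending RFP, 1.36% of arch and 0.161% of descending cells. Cluster 16, of low UMI count, made up 0.591, 0.376, 0.634, 1.80, 0.676 and 3.85% of these libraries in the same order. The myeloid-like cluster 18 made up at most 0.117% of any library, with 0 of 2999 cells in ascending GFP, which allows up to 0.10% (3 counts). The clusters that hold most of the pool differed between libraries. Cluster 3 held 45.0% of the root GFP and 36.1% of the root RFP pool, cluster 5 held 41.5% of ascending GFP, cluster 1 held 28.8% of ascending RFP and 33.1% of the arch, and cluster 7 held 92.8% of the descending pool.

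The first comparison set GFP cells, descended from Nkx2-5-expressing progenitors, against RFP cells of the same segment. GFP cells had more transcripts of the small proteoglycan decorin (Dcn), the muscle intermediate filament desmin (Des) and the G-protein regulator Rgs5 in both root and ascending aorta. Dcn was at 87.2 CPM in GFP and 29.6 CPM in RFP cells of the root, 2.95-fold (2.78 to 3.13), and at 71.0 and 8.60 CPM in the ascending aorta, 8.25-fold (7.75 to 8.79). Within clusters of at least 50 cells of both lineages in the ascending aorta the Dcn difference was smaller, with a median log2 ratio of 0.91 and at most 1.43, against 2.48 in the pool. Des was 2.43-fold higher in GFP cells of the root (2.37 to 2.49) and 3.87-fold higher in the ascending aorta (3.76 to 3.97). Rgs5 was 2.19-fold (2.09 to 2.31) and 2.58-fold higher (2.51 to 2.65), but within clusters of the root its median log2 ratio was 0.12. The matricellular gene Ccn5 was lower in GFP cells, at 36.5 against 63.5 CPM in the root and 34.2 against 88.0 CPM in the ascending aorta, folds of 1.74 (1.65 to 1.83) and 2.58. Under the stricter cell filter its log2 ratio in the root went from -0.72 to -0.47, below 1.5-fold.

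At 1.5-fold, 9 genes were higher and 2 were lower in GFP cells of both segments, among 5763 genes compared. The other 6 higher genes were Rab6b, a Golgi GTPase, at 2.18-fold in the root and 2.07-fold in the ascending aorta, Zfp503, a zinc finger gene, at 1.83 and 2.40, the large proteoglycan gene versican (Vcan) at 1.89 and 1.66, Bmp3, of the BMP family, at 1.65 and 1.78, Psd at 1.68 and 4.63, and the DNA polymerase subunit gene Pola2 at 1.80 and 2.51. Within clusters the median log2 ratio of Rab6b was 0.50 in the root and 0.31 in the ascending aorta, where 1 of 8 clusters reached 1.5-fold, against 0.99 and 0.89 in the pool. Over all 11 shared genes and clusters it was 0.64 in the root and 0.68 in the ascending aorta, against 0.75 and 1.03 for the genes in the pool. With cells thinned to 2000 UMIs Bmp3 fell below 1.5-fold in the root, with a log2 ratio of 0.55. Taken singly, 14 genes were higher and 6 lower in GFP cells of the root, and 28 were higher and 21 lower in the ascending aorta. The overlap of independent lists of these lengths is 0.0680 higher and 0.0219 lower genes, and 0 genes were 1.5-fold apart in opposite directions. Across genes, which are not independent replicates, the log2 ratios of root and ascending aorta had a Pearson r of 0.574, a Spearman rho of 0.364 and a covariance of 8.53e-03.

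**Figure D1:**
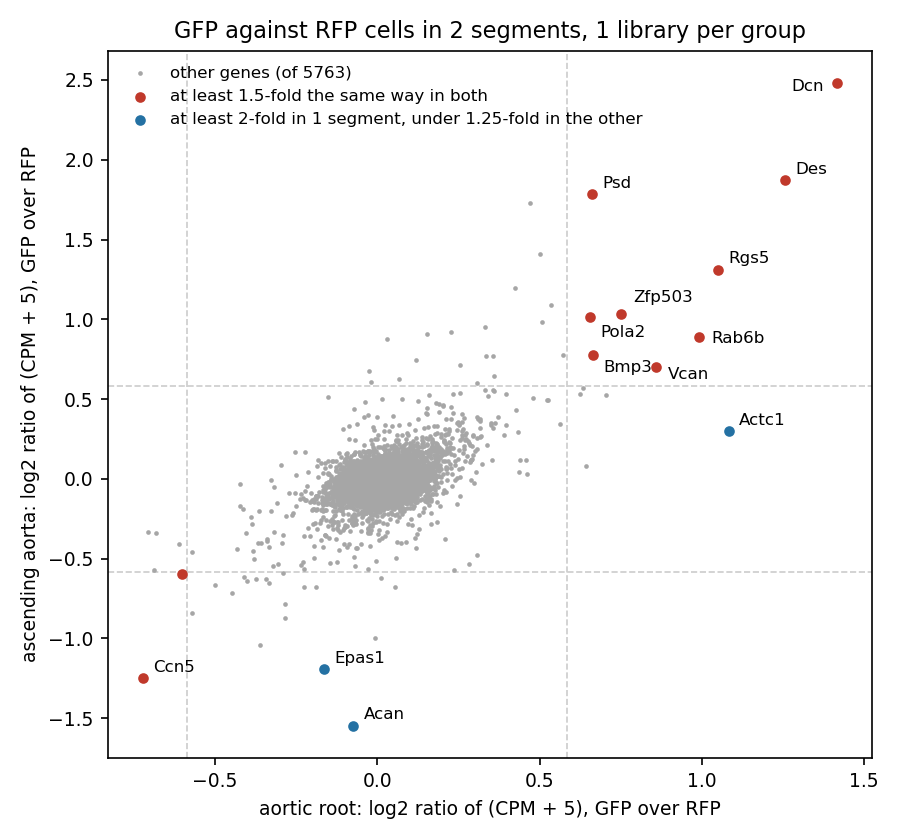
Log2 ratio of CPM plus 5 in GFP over RFP cells, in the root (x axis) and the ascending aorta (y axis), for 5763 genes, with dashed lines at 1.5-fold. Red points are the 11 genes at least 1.5-fold apart the same way in both segments, such as Dcn at 1.42 and 2.48, and blue points are Actc1, Epas1 and Acan, at least 2-fold apart in 1 segment and below the limit of the naming rule in the other.

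Dcn lies on chromosome 10 (97479609 to 97518143, plus strand), Des on chromosome 1 (75360329 to 75368579, plus), Rgs5 on chromosome 1 (169655501 to 169695813, plus), Vcan on chromosome 13 (89655312 to 89742509, minus) and Ccn5 on chromosome 2 (163820861 to 163833146, plus), all as protein-coding genes. Markers of other cell types also differed between lineages. Cluster 13, which lies outside the pool, had a larger share in GFP than in RFP cells of both segments, as given above. The summed fibroblast markers within the pool were 746 CPM in GFP and 761 CPM in RFP cells of the root, and 706 and 691 CPM in the ascending aorta, but these sums are set by Gsn, at 390 and 529 CPM in the root and 401 and 546 CPM in the ascending aorta. Without Gsn and Dcn they were 269 and 202 CPM in the root and 234 and 136 CPM in the ascending aorta. Cardiomyocyte markers summed to 1005 CPM in GFP and 720 CPM in RFP cells of the root, and to 452 and 166 CPM in the ascending aorta, mostly from Tnnt2, at 911 and 657 CPM and at 394 and 115 CPM. Chondrocyte markers went the other way in the ascending aorta, at 22.8 CPM in GFP and 65.2 CPM in RFP cells, mostly from Acan, and stood at 64.1 and 63.4 CPM in the root. Pericyte markers summed to 432 and 372 CPM in the root and 602 and 516 CPM in the ascending aorta.

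A few genes were at least 2-fold apart between lineages in 1 segment and below the limit of the naming rule in the other, on the scale of CPM plus 5. Actc1, the cardiac alpha-actin gene, was 2.61-fold higher in GFP cells of the root (2.37 to 2.87; 29.9 against 11.5 CPM). In the ascending aorta its ratio without the pseudocount was 2.06-fold (1.65 to 2.56), at 2.90 and 1.41 CPM, and with a pseudocount of 1 it passed the 1.5-fold rule in both segments. Actc1 is close in sequence to Acta2, so a share of its counts is uncertain. Actc1 also leads cluster 12, which held 590 of 5461 pooled root GFP and 216 of 3878 pooled root RFP cells. That cluster held 6 ascending GFP and 4 ascending RFP cells, and the Actc1 ratio within clusters was not taken. In the ascending aorta, the cartilage proteoglycan gene Acan was 3.64-fold lower in GFP cells (3.35 to 3.95; 13.5 against 48.9 CPM), and the hypoxia-inducible factor gene Epas1 2.45-fold lower (2.33 to 2.57). In the root Acan stood at 37.3 and 39.5 CPM and Epas1 at 104 and 117 CPM. Whether these effects differ between segments was not tested. The contractile genes themselves were close. Acta2 stood at 20719 CPM in GFP and 21830.1 CPM in RFP cells of the root, Myh11 at 6698 and 6091 CPM, and the sort marker Itga8 at 1592 and 1524 CPM. Elastin (Eln) stood at 1517 and 1542 CPM in the root and at 2021 and 2560.4 CPM in the ascending aorta, 1.27-fold lower in GFP cells there (1.26 to 1.28).

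Most members of the fixed lists were less than 1.5-fold apart between lineages. Among 6122 genes that reached 20 CPM in a library, 99.6% lay within 1.5-fold in the root and 99.1% in the ascending aorta. Lists with several members set apart, such as the modulated genes, thus held a larger share of such genes than these 6122 genes did. The shares are at unlike minima, since list members were counted from 5 CPM in one of the libraries compared. Of 26 contractile genes 1 was higher in GFP cells of the root, Des, and in the ascending aorta 2 were higher and 1 lower, with Actg2 at 285 against 181 CPM and Sncg at 73.3 against 116 CPM. Their median log2 ratio was 0.08 in the root and 0.05 in the ascending aorta, at percentiles 99.99 and 99.83 of the random lists. Collagens had medians of 0.16 and 0.08, with Col14a1 1.74-fold higher in the ascending aorta as the single one of 15 set apart. Elastic fibre genes had 1 of 14 higher in the root and 2 of 14 in the ascending aorta, among them Loxl2 at 25.2 against 12.7 CPM. Genes of modulated smooth muscle and proteoglycans had 3 higher and 1 lower of 18 in the root, and 3 higher and 3 lower of 17 in the ascending aorta. Of the cardiac and second heart field genes, 1 of 14 was higher in the root, Isl1, and in the ascending aorta 2 of 12 were higher and Tbx20 was lower, at 14.9 against 34.7 CPM. Of the Notch and PDGF genes, 0 of 11 were set apart in the ascending aorta, with a median of -0.15 at percentile 0, and Notch3 at 17.6 against 28.5 CPM. Of 8 chemokine and inflammation genes there, Cxcl12 was higher, at 64.6 against 31.7 CPM, and 1 vasoactive gene, Rgs5, was higher in each segment. No measured member of the TGF-beta and BMP, neural crest, Hox, immediate early, oxidative phosphorylation or cell cycle lists was 1.5-fold apart in CPM plus 5 between lineages in either segment. Few members were measured of the neural crest (9 of 22 in the root, 10 of 22 in the ascending aorta), Hox (7 of 28) and cell cycle lists (5 of 17). At low CPM the pseudocount also shrinks ratios. Sox9 stood at 7.89 CPM in root GFP and 4.35 CPM in root RFP cells. Snai2 stood at 6.26 CPM in ascending GFP and 10.7 CPM in ascending RFP cells.

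RFP cells were then compared along the aorta, from root to descending segment, to find what sets each segment apart. The descending library differed most, with several Hox genes, which specify position along the body axis, high there and near 0 elsewhere. Hoxa7 (chromosome 6, 52214491 to 52221854, minus strand) stood at 82.4 CPM against 0.105 in the next library, 784-fold (489 to 1348), Hoxb6 at 38.4 against 0.284 CPM, 135-fold (98.7 to 189.9), and Hoxb5 at 33.2 against 0.526 CPM, 63.1-fold (49.9 to 80.9). Hoxb7 stood at 35.1 CPM against 1 count in the next library, a ratio of 1659 (297 to 65560.0), and Hoxb8 at 28.3 CPM against 3 counts, a ratio of 1327 (453 to 6443). The axon guidance gene Sema3a was 28.8-fold higher (24.6 to 33.8), and Tnc, the gene of the matrix protein tenascin C, 5.85-fold higher. The transcription factor gene Hand2 (chromosome 8, 57320983 to 57324633, plus), which acts in heart and branchial arch development, was lowest there, at 0.804 against 94.7 CPM, 118-fold (82.4 to 175), and its divergent neighbour Hand2os1 164-fold lower (79.6 to 408). The counting of strands is not given in the sources used here, so the division of counts between Hand2 and Hand2os1 is uncertain. The growth factor binding gene Igfbp4 was 11.9-fold lower (10.5 to 13.5).

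Pi16, a peptidase inhibitor gene of adventitial fibroblasts, Adamtsl1, Tshz2 and Prrx2 set the arch library apart. Pi16 stood at 34.7 CPM in the arch against 0.375 in the next library, 92.5-fold (55.1 to 169), Adamtsl1 at 36.7 against 1.59 CPM, 23.2-fold (18.4 to 29.5), Tshz2 at 21.8 against 1.82 CPM, and Prrx2, a homeobox gene of mesenchyme, 5.56-fold higher (5.18 to 5.98). The Wnt antagonist genes Frzb and Sfrp2 were 2.85-fold and 2.31-fold higher. Pi16 lies on chromosome 17 (29317680 to 29330593, plus) and Adamtsl1 on chromosome 4 (85514172 to 86428385, plus). Fibroblast markers summed to 943 CPM in the arch pool, against 691 in the ascending RFP pool and 452 in the descending one. Without Gsn and Dcn the sums were 239, 136 and 71.1 CPM, with Col14a1 at 185 CPM in the arch and 120 in the ascending RFP pool, and Pi16 among them. Des was 2.08-fold lower in the arch than in the next library, at 31.3 against 64.9 CPM.

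The root library stood out for Tnnt2, the cardiac troponin T gene (chromosome 1, 135836354 to 135852260, plus). It was at 657 CPM in the root against 115 in the ascending aorta, 5.70-fold (5.6 to 5.80), and at 22.4 CPM in the arch and 11.3 in the descending aorta. Corin, the protease that activates natriuretic peptides, was 20.6-fold higher (18 to 23.8), the collagen gene Col8a1 5.51-fold (4.97 to 6.12), ceruloplasmin (Cp) 3.70-fold (3.46 to 3.95) and the calcium pump regulator phospholamban (Pln) 3.03-fold (2.87 to 3.19). Genes lowest in the root were the retinol carrier Rbp4, 2.29-fold, the microfibril gene Mfap5, 2.28-fold, and the potassium channel regulator Abcc9, 2.35-fold. The summed cardiomyocyte markers were 720 CPM in root, 166 in ascending, 73.0 in arch and 75.9 in descending RFP cells. Elastin ran the other way, at 1542 CPM in root, 2560.4 in ascending, 2721 in arch and 3353 in descending RFP cells.

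Of 6087 genes, 73 were at least 1.5-fold highest and 58 lowest in the descending library, 26 and 40 in the root, 18 and 1 in the arch, and 0 and 0 in the ascending aorta. With TMM size factors the split in the descending library was 46 highest and 73 lowest, and with median-of-ratios size factors 48 and 71. The root split became 30 and 30 with median-of-ratios size factors. Over 6122 genes, the log2 ratio of descending to ascending RFP cells had an SD of 0.30, against 0.15 for arch to ascending and 0.17 for root to ascending, and 96.7% of genes lay within 1.5-fold. The median of all genes was 0.10 in the descending library against ascending, and TMM moved it by -0.14, so its ratios are relative to this shift.

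**Figure D2:**
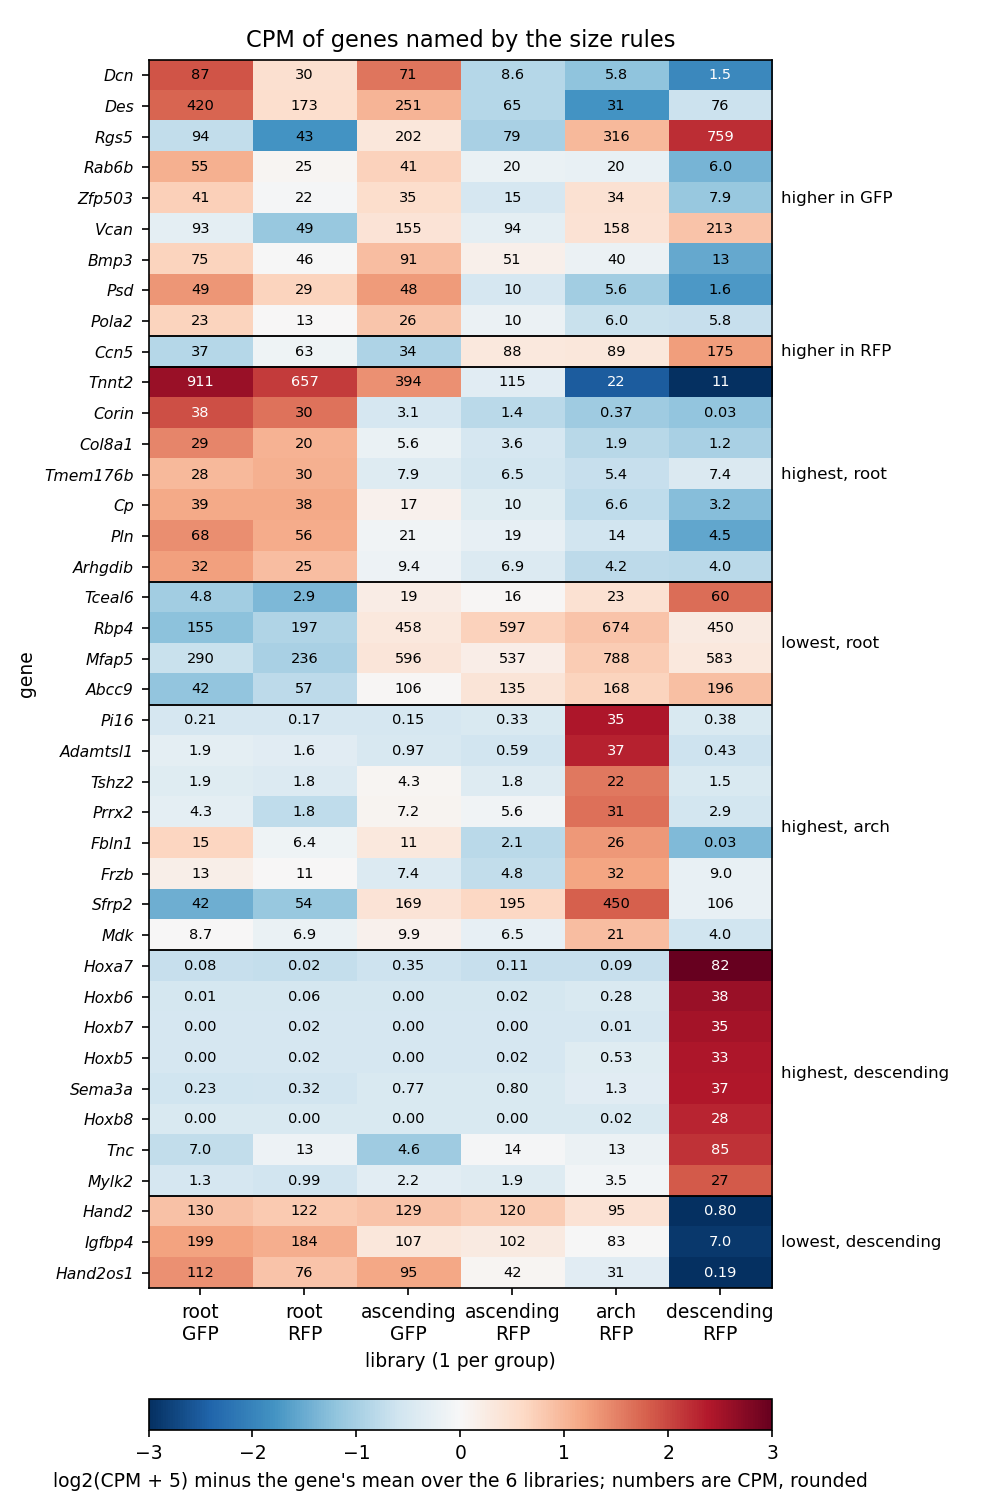
CPM of named genes (one per line) in the 6 libraries (columns), with the CPM printed in each field and colour for log2 of CPM plus 5 minus the mean of the gene. Hoxa7 is at 82.4 CPM in the descending and at most 0.105 CPM in the other RFP libraries, and Tnnt2 runs from 657 CPM in root RFP to 11.3 CPM in descending RFP cells.

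Set against the ascending aorta, lists showed what each segment shared. In the descending library 10 of 13 measured Hox genes were higher and 0 lower, with a median log2 ratio of 1.53 at percentile 100 of random lists. The median is 1.53 also with Hoxb7 and Hoxb8, at 0 counts in the ascending library, set at their bound. Vasoactive genes had 4 of 16 higher there and 0 lower, with a median of 0.41 at percentile 100. Rgs5 was 9.66-fold higher (9.46 to 9.87; 759 against 78.6 CPM), the ATP receptor gene P2rx1 3.22-fold and the natriuretic peptide receptor gene Npr1 1.71-fold. Pericyte markers, which share Rgs5 with this list, summed to 1329.6 CPM in the descending and 516 CPM in the ascending RFP pool. Collagens had 2 of 14 higher, Col6a2 and Col6a1 at 1.68-fold and 1.55-fold, and 1 lower. Among contractile genes Sncg was 3.69-fold and Pln 4.12-fold lower, with 0 of 26 higher, and among cardiac genes 1 of 10 was higher and 3 were lower, with Tbx20 9.66-fold lower, at 3.59 against 34.7 CPM. In that library 0 higher and 2 lower of 13 elastic fibre genes, 3 higher and 3 lower of 15 modulated genes, 0 higher and 1 lower of 8 neural crest genes, 1 higher of 7 chemokine genes and 1 higher of 21 immediate early genes were set apart.

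The arch had the neural crest list apart, with 6 of 13 genes higher than in the ascending aorta, 0 lower and a median of 0.54 at percentile 100. The homeobox genes Dlx6, Dlx5 and Msx2 were 14.9-fold (12.6 to 17.7), 7.59-fold (6.71 to 8.61) and 13.7-fold higher (11.1 to 17.2), at 13.7, 13.8 and 7.82 CPM. Prrx2, Sox9 at 14.3 against 4.09 CPM and the endothelin receptor gene Ednra at 10.2 against 4.71 CPM were the others. In the arch, 2 of 18 vasoactive genes were higher, with Rgs5 4.03-fold. Pericyte markers, Rgs5 among them, summed to 806 CPM in the arch and 516 CPM in the ascending RFP pool. Of 26 contractile genes 1 was higher in the arch, Actg2 at 315 against 181 CPM, and 1 lower, Des. The contractile median was -0.05 at percentile 0.07. Collagens and elastic fibre genes had 1 higher each, of 14. Modulated genes had 3 of 16 higher and 0 lower, among them Vcan at 158 against 93.5 CPM, but a median of -0.09 at percentile 0. That median turned positive with every barcode (3.76e-03) and without an expression minimum (0.05). Tbx20, at 14.5 CPM, was the 1 cardiac gene of 10 lower.

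Root and ascending aorta were also compared within each lineage, and most genes set apart in RFP cells were set apart in GFP cells too. Corin was 20.6-fold higher in the root in RFP cells and 12.6-fold in GFP cells (10.6 to 15), Pln 3.03-fold and 3.21-fold, Apoe 2.34-fold and 2.68-fold, and Actc1 8.14-fold and 10.3-fold. Sfrp2 was lower in the root, 3.58-fold in RFP (3.44 to 3.73) and 3.99-fold in GFP cells (3.83 to 4.16), as were Rbp4, 3.03-fold and 2.96-fold, Mfap5, 2.28-fold and 2.05-fold, and the channel regulator Abcc9, 2.35-fold and 2.51-fold. At 1.5-fold, 26 genes were higher and 29 lower in the root in both lineages, out of 35 and 44 in RFP and 47 and 46 in GFP cells, where independent lists would share 0.285 and 0.351. Across genes r was 0.764 and rho 0.528, with a covariance of 0.0229. In RFP cells the split of 35 higher and 44 lower, 44.3% higher, became 42 and 33, 56.0% higher, with median-of-ratios size factors.

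By list, vasoactive genes were lower in the root, 4 of 17 in RFP and 4 of 18 in GFP cells with 0 higher, and medians of -0.26 and -0.19 at percentile 0, with Npr1 at 43.4 against 103 CPM and Rgs5 at 42.8 against 78.6 CPM in RFP cells. Hox genes had medians of -0.38 and -0.40, with Hoxb2 the 1 of 7 set apart, at 16.6 against 30.4 CPM in RFP cells. Collagens had medians of -0.23 and -0.16, with 1 higher and 1 lower of 15 in RFP cells and 1 higher in GFP cells. Contractile genes had 3 of 26 higher in RFP and 4 in GFP cells, and 0 lower, with Des at 173 against 64.9 CPM in RFP cells. Cardiac genes had 2 of 12 higher in RFP and 2 of 14 in GFP cells, with medians of 0.04 and 0.03 and Gata4 5.98-fold higher in RFP cells and 7.38-fold in GFP cells. Modulated genes had 4 higher and 2 lower of 17 in RFP cells and 5 higher and 2 lower of 18 in GFP cells, with Thbs1, the thrombospondin 1 gene, at 17.8 against 2.11 CPM in RFP cells. Notch and PDGF genes had a median of 0.20 in GFP cells, with Notch3 at 33.1 against 17.6 CPM.

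**Figure D3:**
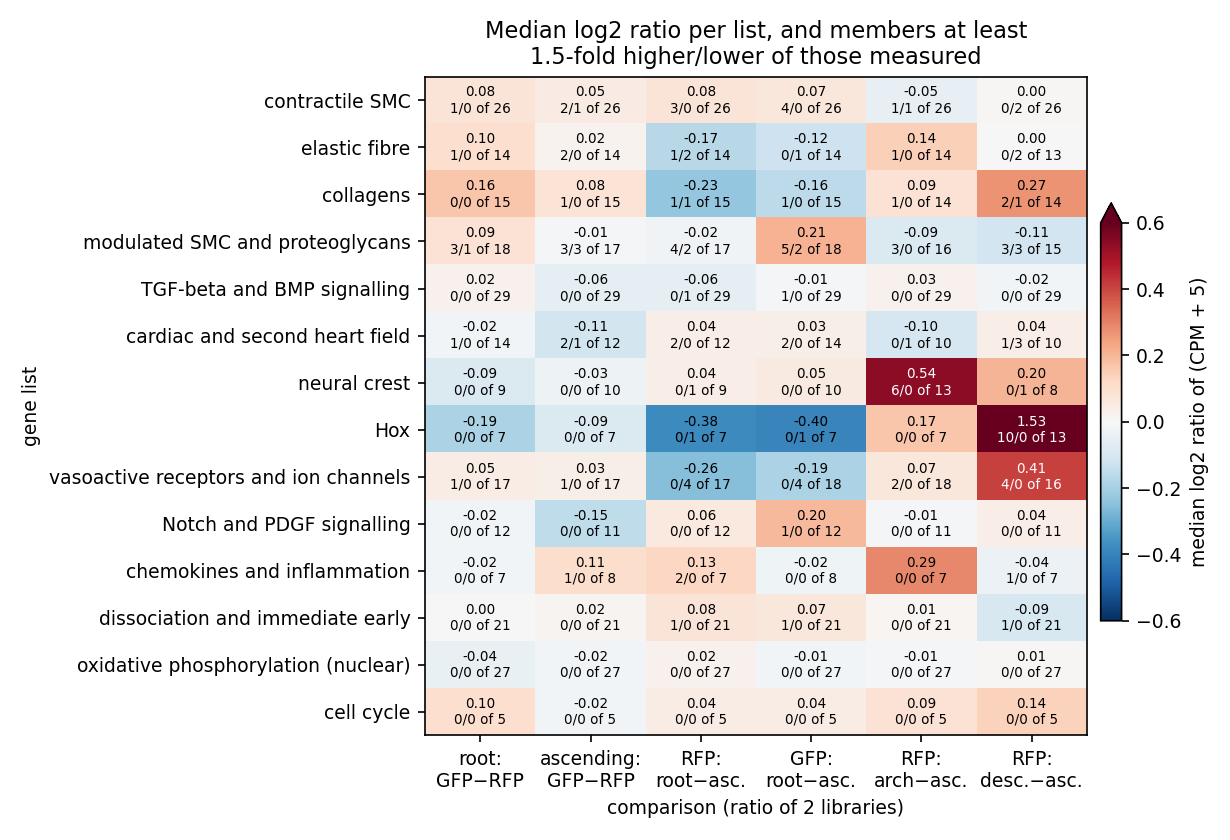
Median log2 ratio (colour) of 14 gene lists in 6 comparisons, with the number of members at least 1.5-fold higher and lower out of those measured printed in each field. Hox genes in the descending against the ascending RFP library have a median of 1.53 with 10 of 13 higher, and neural crest genes in the arch 0.54 with 6 of 13 higher.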

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

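The tests given in this part were chosen only after the results they bear on had been seen. Acan differed between root and ascending aorta in opposite directions in the 2 lineages, with a log2 ratio of root to ascending of -0.28 in RFP and 1.20 in GFP cells, and this difference was not tested. Cells outside the pool held signals of their own. Cluster 13, led by fibroblast markers, made up 4.45% of root GFP cells, and the myeloid-like cluster 18 made up 0.117% of ascending RFP cells, although the sort was for ITGA8. Cluster 18 also had Acta2 at 9464 CPM and Myh11 at 3590 CPM, and doublets were in effect not removed.

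Genes shared by both segments between lineages could come from a different mix of clusters in GFP and RFP cells, but within clusters that hold at least 50 cells of both lineages the median stayed at 1.5-fold or more in both segments for 6 of the 11 genes, Dcn, Des, Psd, Pola2, Bmp3 and Ccn5. This argues against the mix as their whole cause, although it may account for part, as the log2 ratio in the ascending aorta fell from 2.48 to 0.91 for Dcn (quartiles 0.59 to 1.17) and from 1.79 to 0.91 for Psd (0.64 to 1.10). Cluster 9, led by Osr2, Isl1, Dcn and Rab6b, is uneven in this way. It held 469 of 2905 pooled ascending GFP cells and 194 of 11703 ascending RFP cells, with Dcn there at 288 and 161 CPM. In the root it held 606 of 5461 GFP and 85 of 3878 RFP cells. For the other 5 the mix cannot be told apart, since clusters formed on the same counts can take up a lineage difference, and their smaller ratios ended the call, as for Rgs5 in the root, from 1.05 to 0.12 (0.03 to 0.87), and Rab6b in the ascending aorta, from 0.89 to 0.31 (0.19 to 0.47). The case that all Dcn of the GFP pools came from RNA or cells like those of cluster 13 sets an upper bound. Such a source would add at most 69.0% of the difference of any of the other 8 higher genes in either segment. This argues against it as the whole cause for those 8 genes. For Dcn itself a share of 2.57% in the root and 11.2% in the ascending aorta would be needed. The other leading genes of cluster 13 gave a median of 0.365% and 2.57%. Cluster 13 was formed on the same counts and left out of the pool, so its leading genes are low in the pool partly by that split. These shares therefore cannot decide for Dcn. Fibroblasts in general stay open, because the other fibroblast markers had a median log2 ratio of 0.36 in the root and 0.43 in the ascending aorta, with Lum higher and Gsn lower in GFP cells, and so does the lineage difference that the design names.

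Tnnt2 and Actc1, highest in the root, might come from RNA or cells of heart muscle, a source that would keep its genes in 1 ratio in every cell. The UMIs of each cell were split at random into 2 parts, 100 times. Cells without an Actc1 UMI in the first part were set against cells with one, by Tnnt2 per Actc1 in the second part. The median ratio was 126 in root GFP (99.4 to 151) and 161 in root RFP (108 to 260). Split by Myh6 and Tnni3, with Tnnt2 taken per these genes, it was 45.1 and 42.5. This argues against 1 source that gives Tnnt2 and these genes together. It cannot place Tnnt2 itself, since an uneven spread of Actc1, Myh6 and Tnni3 over cells raises the ratio whatever the origin of Tnnt2. For Actc1 heart muscle cannot be told apart either. Myh6 and Tnni3 had 29.8 and 46.8 UMIs per 100 Actc1 UMIs in root GFP and RFP, and Myl2, Myl7, Nppa and Mb together 0.489 and 1.66. Reads shared between Actc1 and its paralog Acta2 are argued against as the whole source of Actc1, since Acta2 per Actc1 was 184 and 239 times higher in cells without than with an Actc1 UMI in the other part. Tnnt2 had 68470 UMIs in the root GFP and 31073 in the root RFP pool, against 2248 and 543 of Actc1. If heart muscle makes Actc1 at a level like that of Tnnt2, it could give only a small part of this Tnnt2. The ratio of the 2 genes in heart muscle was not measured here. Expression of Tnnt2 by smooth muscle cells of the root stays a hypothesis found on the same data, with RNA or cells of heart muscle not excluded.

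Genes highest in the arch might come from adventitial fibroblasts. The other fibroblast markers had a median log2 ratio of 0.28 to the ascending aorta, and Col14a1 and Fbln1 were higher in arch cells with a Pi16 UMI than in those without, at 386 against 159 and 154 against 9.07 CPM, but Dcn was lower, at 3.52 against 6.05 CPM. The 7 markers that are low in the ascending aorta summed to 0.0227 CPM more in the arch, a net of Lum higher and Dcn lower. In the pooled arch cells with a Pi16 UMI they summed to 10.997 UMIs per 100 Pi16 UMIs (10.04 to 12.02). In the 11 arch cells of cluster 13 with a Pi16 UMI the value was 551 (438 to 698). Cluster 13 was left out of the pool because fibroblast markers, Dcn and Lum among them, lead it. The lower value in the pool was thus largely set by that split, and adventitial fibroblasts stay open. Arch cells with a Dlx5 or Dlx6 UMI held a Pi16 UMI in 42.6% of 1060 cells, against 4.24% of 10222 others, when thinned to 5000 UMIs, an odds ratio of 16.8 (14.3 to 19.7), and in 47.2% and 5.31% unthinned, with 299 shallower cells left out of the thinned ones. A Pi16 UMI was found in 7.84% of thinned arch and 0.165% of thinned ascending RFP cells, and arch cells with one had less Acta2, at 15212 against 20511 CPM, so a subset of arch cells that carries these genes together stays as a hypothesis, to which cluster 8, led by them and formed on the same counts with 13.7% of the arch pool, adds no separate evidence.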

How the results depend on the processing

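Removing the top 5% of doublet scores and taking ratios within clusters were settings chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because each group is 1 library and the groups share fewer than 2 replicate numbers. The edgeR fit given here takes segment, not a replicate number, as a covariate. All 185 gene ratios at 1.5-fold or more kept their direction in the 12 settings that recompute them, and 166 stayed at 1.5-fold in all of these. Of the list medians, 966 of 1092 values moved by less than the half-width of the random-list range and 126 by more, and of the gene ratios 902 of 5412 values moved by more than the half-width of their counting interval. The cause of the moves below was not tested, except where fewer cells, a larger fold or a lower minimum changes a count by construction. Genes higher in GFP cells in both segments numbered 9, and 16 with a pseudocount of 1, 18 with an expression minimum of 5 or with none, and 3 at 2-fold. Genes higher in RFP cells in both segments numbered 2, and 1 under the stricter filter or with every barcode. They numbered 4 with the mean of each cell's CPM, with cells thinned to 2000 UMIs and with a minimum of 5 or none, 6 with a pseudocount of 1 and 0 at 2-fold. The edgeR fit tests 1 lineage effect over both segments, without a fold limit and without a demand on each segment. At an adjusted p of 0.05 it gave 42 genes higher in GFP cells, 8 of the 9 among them, and 28 higher in RFP cells. These counts are therefore not of the same kind as the 9 and 2. The correlation across genes of the root and ascending lineage ratios, 0.574, became 0.542 under the stricter filter, 0.594 with every barcode, 0.388 with thinned cells, 0.555 with a minimum of 5 and 0.534 with none. Thinning gave 2 genes lowest in the ascending library in place of 0, and TMM gave 46 genes highest in the descending library in place of 73. The pooled share in root GFP, root RFP, ascending GFP, ascending RFP and arch was 99.4, 99.5, 99.4, 98.1 and 99.2% at resolution 0.4. At resolution 1.5 it was 93.9% in root GFP, 95.6% in ascending GFP and 97.0% in the arch. Under the looser filter it was 80.4, 86.0, 87.0, 75.4, 88.1 and 78.6% in the 6 libraries. The stricter filter passed 3150 root GFP, 1597 root RFP, 1399 ascending GFP and 3638 ascending RFP cells. With 37309468 UMIs in the descending pool, a count of 0 there allows a level of up to 0.0804 CPM.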

Other observations

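Of the tests in this part, the one on position along the aorta was written before its result was seen, and the genes named here were chosen after their values were seen. Isl1, a transcription factor gene of second heart field progenitors, stood at 10.1 CPM in root GFP and 2.30 CPM in root RFP cells, 4.39-fold (3.59 to 5.42), and at 9.53 and 1.59 CPM in the ascending aorta, 6.0-fold (5.13 to 7.03). It stood at 0.263 CPM in the arch and had 0 counts in the descending library. Osr2, a zinc finger gene, was 4.19-fold higher in GFP cells of the root (3.13 to 5.71) and 7.68-fold in the ascending aorta (6.52 to 9.08). The proteoglycan gene Lum was 2.43-fold and 4.85-fold higher. These 3 genes lie under the minimum of 20 CPM. Isl1 and Osr2 are leading genes of cluster 9, which held 11.1% of the root GFP and 16.1% of the ascending GFP pool. Whether their ratios hold outside that cluster was not tested.

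Gata4, a cardiac transcription factor gene, differed more between segments than between lineages, at 15.6 and 17.0 CPM in root GFP and RFP cells, 2.11 and 2.85 CPM in the ascending aorta, 3 counts in the arch and 0 in the descending library. Its GFP to RFP ratio was 0.913 in the root (0.834 to 1.0) and 0.740 in the ascending aorta (0.587 to 0.923). Gt(ROSA)26Sor, the transcript of the locus that carries the mT/mG reporter, was 1.88-fold higher in GFP than in RFP cells of the root (1.71 to 2.06) and 1.59-fold in the ascending aorta (1.48 to 1.71), and stood at 14.5 CPM in the arch and 13.8 CPM in the descending library.

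Lineage ratios might mirror position, if GFP cells lay nearer the root within a segment. Across genes, which are not independent replicates, the ascending lineage ratio had an r of 0.134 with the ratio of root to arch RFP cells, and the root lineage ratio an r of -0.0476 with the ratio of ascending to arch RFP cells. The second lies below the bound of 0.1 set for this hypothesis, and the first lies above it. The ratio of ascending to arch cells measures position beyond the root, not within it. The second value therefore cannot decide for the root, and the hypothesis stays open.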
